A study of Pyrus communis x Pyrus pyrifolia and Pyrus pyrifolia and Pyrus communis with 12 samples.

How the data were processed

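RNA from pear flowers was measured on 1-colour Agilent oligonucleotide arrays. Flowers of 6 cultivars were taken 1 day before bloom in 2009 and again in 2010, which gives 12 arrays. Per the labels, La France and Taiheiyou have high parthenocarpy, the setting of fruit without fertilisation, and Housui, LeConte, Okusankichi and a hybrid line of La France and Housui have low parthenocarpy. La France is a European pear (Pyrus communis). Housui and Okusankichi are Japanese pears (Pyrus pyrifolia). The hybrid line is called here the La France × Housui hybrid, after the parents its label gives, and the label of Taiheiyou gives La France and Okusankichi. LeConte is described as a hybrid. Per the labels' protocols, RNA was amplified and labelled with a low-input linear amplification kit. The labels state no replicate array of a cultivar within a year, so the cultivar was the unit of replication.

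The 2 years used different array designs, so year and design cannot be told apart. The 2009 design holds 18872 probes and the 2010 design 21681, mostly with 2 spots each. Per the file headers, spots were quantified with Agilent Feature Extraction, version 9.5.3.1 in 2009 and 10.7.1.1 in 2010. The deposited scanner files give processed signal as an intensity on a linear scale, and flags for outlier, saturated and well-above-background spots. Per the 2009 headers, spatial and multiplicative detrending were on, and the setting for background correction was off. The 2010 headers used here do not give these settings. The authors' deposited value tables hold log2 values. Set against the scanner values, they were scaled to each array's 75th percentile and centred on each probe's median over the 6 arrays of its year. Pearson's r across probes was at least 0.999999 on every array, with slopes near 1. The direction and scale of that table are therefore known, and its column medians lie between -0.0494 and 0.14 in 2009 and between -0.0658 and 0.0594 in 2010.

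Probes of the 2009 design are 60 bases long, and often a pair of names shares a stem and ends in F and R. A shared stem was taken here to mark the same clone, which the files do not state. The files pair no probe with a gene name or description, so probes are given by name. Of the 2010 probes, 9812 carry the name of a 2009 probe with a fixed suffix. These were taken as the same probe. Over those tested in both years, mean level in 2009 correlated with mean level in 2010 at r = 0.97, across probes, which are not independent replicates. No sequences are given in the 2010 files.

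Log2 processed signal minus each array's 75th percentile was the main value. Control spots and spots flagged as outliers were left out and the spots of a probe were averaged. A probe counted as detected where at least 0.5 of its spots were well above background, and was tested if detected on at least 2 of the 6 arrays of a year. High and low cultivars were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjusted p under 0.05 as the threshold for a call. Each year was fitted alone. For both years, each cultivar's mean over its 2 arrays was fitted over the shared probes. The change of the difference between years was tested on each cultivar's 2010 minus 2009 value. Whether a cultivar's name held the same material in both years was tested with an exact permutation of the 720 pairings. P-values measure the spread between cultivars, which differ in species and parentage as well as in parthenocarpy.

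The groups hold 2 and 4 cultivars, and this number limits the precision. Arrays were simulated with the real spreads shuffled among probes and with 200 changed probes. The fit of 2009 recovered 0% of changes of 1 log2 unit, 48% of 2 units, 84% of 4 units and 96% of 8 units. The shares were 0%, 30%, 64% and 98% for 2010, and 22%, 68%, 96% and 100% for both years. For the change between years they were 4%, 28%, 68% and 100%. With 200 changed probes the adjusted threshold is easier to reach than with the few calls of the real fits. The shares may therefore be too high for the real data.

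Before the data were examined, a rule was fixed for the items to name. From the fit of both years it took up to 10 called probes per direction whose high cultivars both lay beyond all 4 low cultivars in each year. A direction with under 5 was filled up to 5 by smallest p, as not past the threshold. The rule asked for a gene name or description, which no probe has, so it was applied to probe names. It gave 11 probes, and at most a pair per direction and comparison is printed, since the names cannot be read as genes. The separate values of the other 5 called probes are left out here. The 18 gene lists fixed at the same time could not be matched to probes and were not tested. For a probe not well above background on any array of a group, the ratio is given as a bound. The bright group's mean was set against the dim group's mean, with each dim array taken at the higher of its own value and its lowest signal among detected probes. Some values above that lowest signal were still not well above background, so the bounds are approximate.

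In 2009 the arrays lay on 2 slides, with Housui and Okusankichi on the second. In 2010 each array had its own slide and scanning fell on 2 days, with Housui and Okusankichi on the second. The batch therefore parts the Japanese pears from the rest, and the batch and the Japanese species cannot be told apart. The other batch holds both high cultivars with the La France × Housui hybrid and LeConte, and values are also given with the batch as a term and within that batch. Alternatives covered background correction by normexp, quantile or median scaling, the filter on dim probes, the deposited value tables, the variance model, a minimum difference, European pear parentage as a covariate, the unit of replication, the 3 hybrids alone and leaving out each cultivar. The parentage covariate was the European share, set at 1 for La France, 0 for the Japanese pears and 0.5 for the hybrids. LeConte is described only as a hybrid, so its share of 0.5 was assumed. The 2010 files used here give no mean signal, so the median signal took its place in normexp (offset 50).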

Results

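Flowers of 6 pear cultivars, 2 with high and 4 with low parthenocarpy, were profiled 1 day before bloom in 2009 and in 2010. The comparison asks which transcripts differ between the groups before flowering. The 75th percentile of signal lay between 917 and 1502 on the 2009 arrays and between 2527 and 7775 on the 2010 arrays. Between 77.2% and 81.0% of probes were detected per array in 2009, and between 76.2% and 85.1% in 2010. No spot was saturated. The median coefficient of variation between spots of a probe lay between 3.11% and 4.95% over the 12 arrays.

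Each cultivar kept its own profile from year to year. Across 8257 shared probes, a cultivar's deviation from its year's mean in 2009 correlated with its deviation in 2010 at a mean Pearson's r of 0.65. La France had the highest r, 0.87, followed by Taiheiyou at 0.76, and Housui had the lowest, 0.45. The highest r between different cultivars was 0.31, between the La France × Housui hybrid in 2009 and Housui in 2010. In an exact permutation test of the 720 pairings (one-sided), p was 0.00139, the smallest they can give. Probes are not independent replicates.

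Over both years, 7 of 8257 probes were called between high and low cultivars, 1 higher and 6 lower in the high group. The probe NFR2_08_57mR was not well above background in La France and Taiheiyou in either year and was bright in all 4 low cultivars. Its mean over both years was -9.80 ± 0.05 (SD, n = 2) in the high and 4.30 ± 0.39 (SD, n = 4) in the low group, on the log2 scale. Within a year the SD of the high group was larger, 0.26 in 2009 and 0.35 in 2010. The SD of 0.05 is thus no measure of precision for a signal near background. The signal of this probe was at least 8769-fold lower in the high group (limma adjusted p = 1.2e-05). The probe NFR6_04_80mR, with the sequence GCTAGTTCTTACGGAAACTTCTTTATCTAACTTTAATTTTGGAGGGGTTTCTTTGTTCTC, was the only call in the other direction. It was 6.90-fold higher in the high group, a log2 difference of 2.79 ± 0.28 (SE, limma adjusted p = 0.041), with means of 3.87 ± 0.17 (SD, n = 2) and 1.08 ± 0.35 (SD, n = 4). For both probes the high cultivars lay beyond every low cultivar in each year. The other 5 called probes were lower in the high group, and 2 of them were not well above background in the high cultivars in 2009.

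**Figure D1:**
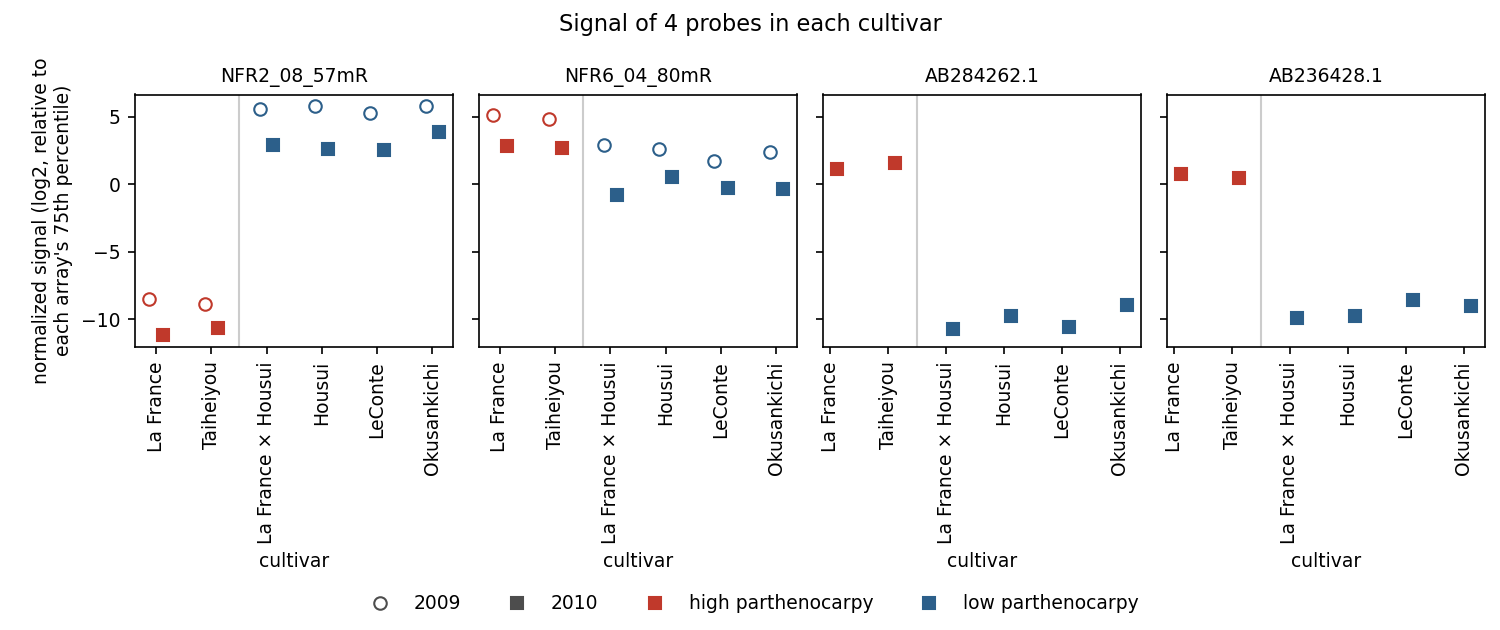
Normalized signal (y axis, log2 relative to each array's 75th percentile) of 4 probes in each cultivar (x axis), with open circles for 2009, filled squares for 2010, red for high and blue for low parthenocarpy; each point is 1 array, and the last 2 probes are on the 2010 design alone. The high cultivars lie beyond all 4 low cultivars for each probe, from -8.50 and -8.87 against 5.29 or more for NFR2_08_57mR in 2009 to 1.09 and 1.57 against -8.96 or less for AB284262.1.

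The calls were also read with the batch and the parentage of the cultivars. The differences of the 7 probes within the batch that holds both groups were 0.91 to 1.07 times those over all cultivars. With the parentage covariate they were 0.85 to 1.08 times as large, and fewer of the 7 were called in each case. A call needs low cultivars that agree, so ratios near 1 follow largely from the choice of these probes. With the batch as a term 2 probes were called, within the batch that holds both groups 5, and with European pear parentage as a covariate 1. Of the 7 calls, only NFR2_08_57mR was among each of these. It was called under all 19 alternatives in which it was tested. Among these, the minimum difference and the deposited value tables could hardly change its call. With normexp background correction the log2 difference of this probe was -9.32, a value that the background and the offset set for the dark arrays. With normexp, 5 of the 7 calls were kept, and the 2 others were the probes not well above background in the high cultivars in 2009. NFR6_04_80mR had limma adjusted p = 0.10 with the batch as a term, 0.14 within that batch and 0.39 with the parentage covariate. It lost the call in 7 of 20 alternatives, and its log2 difference was 2.66 or more in all of them. Without Taiheiyou, which leaves La France alone in the high group, 88 probes were called. Without La France 2 were called, without the La France × Housui hybrid also 2, and without LeConte 19.

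A clone is often covered by other probes, and these did not always show the same difference. For the 7 called probes, 12 other probes of the same clones were on the arrays, and for 8 of them both high cultivars lay beyond all 4 low cultivars on the same side. The other 2009 probe of the clone of NFR6_04_80mR differed by 3.76 (log2, high minus low). The other 2009 probe of the clone of NFR2_08_57mR was not well above background in the high cultivars and was so in only 2 of the 4 low cultivars. A further 2010 probe of that clone differed in the opposite direction, by 0.717, and was well above background in both high and 2 of the 4 low cultivars. Over 5690 clones with both 2009 probes detected on all 6 arrays, high minus low correlated between the probes of a clone at r = 0.56, across clones, which are not independent replicates.

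In 2009, 5 of 15634 probes were called, 1 higher and 4 lower in the high group, and NFR2_08_57mR led them with a signal at least 10606-fold lower (limma adjusted p = 4.8e-06). With the slide as a term 4 probes were called, 2 of them among the 5, and within the slide that holds both groups 6, again 2 of them among the 5. The differences of the 5 probes within that slide were 0.96 to 1.05 times those over all 6 arrays, and 0.94 to 1.08 times with the parentage covariate. As above, ratios near 1 follow largely from the choice of these probes. With the parentage covariate 2 were called. With normexp background correction 13 were called, 3 of them among the 5, and with a variance trend and robust fit 12. Leaving out Taiheiyou gave 65 calls, LeConte 22, Okusankichi 12, La France 3, Housui 2 and the La France × Housui hybrid also 2.

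In 2010, 33 of 18644 probes were called, 8 higher and 25 lower in the high group. The high cultivars lay beyond all low cultivars for each of the 33. A group of 5 called probes from 5 clones, NFR2_08_57mR among them, was not well above background in La France and Taiheiyou and was bright in the 4 low cultivars. Their signal was lower in the high group by at least 7250-fold to 8175-fold. Within each low cultivar the 5 probes lay within 0.294 log2 units of each other, so they need not read separate transcripts, which was not tested. Some clones were called by more than 1 probe, so the 33 calls are not 33 separate transcripts. The opposite pattern was seen for 6 called probes that carry public sequence identifiers in place of clone names. They were well above background in La France and Taiheiyou and in no low cultivar. AB284262.1 was at least 1287-fold higher in the high group (limma adjusted p = 0.00078), with a mean of 1.33 ± 0.34 (SD, n = 2) against -9.99 ± 0.81 (SD, n = 4). AB236428.1 was at least 651-fold higher (limma adjusted p = 0.00050), with a mean of 0.61 ± 0.21 (SD, n = 2) against -9.30 ± 0.62 (SD, n = 4). These 6 and their examples were chosen after their values were seen, and the files do not pair the identifiers with genes. Of the lower probes, 11 were detected on all 6 arrays, with log2 differences between -5.37 and -2.38.

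With scan day as a term 16 probes were called in 2010, 9 higher and 7 lower, and 12 of the 16 were among the 33. Within the scan day that holds both groups 18 were called, 10 of them among the 33. With the parentage covariate 11 were called, and 5 when a probe had to be detected on all 6 arrays. Leaving out Taiheiyou gave 220 calls, LeConte 73, the La France × Housui hybrid 21, Housui 19 and La France 13.

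The differences between high and low cultivars went together in the 2 years. Across the 8257 shared probes, high minus low in 2009 correlated with that in 2010 at r = 0.84, across probes. The same cultivars form both differences, and the 14 other splits of the cultivars into 2 and 4 gave r between 0.44 and 0.78, with a median of 0.64. Of the shared probes, 3 were called in 2009 and 12 in 2010, and all 3 were among the 12, which is no independent repeat, since the cultivars are the same. All 12 differed in the same direction in 2009. No probe was called by limma for a change of the difference between years, and 193 had an unadjusted p under 0.05, where 413 are given by chance. In the simulation this fit recovered 28% of changes of 2 log2 units. Neither the lack of calls nor the count of 193 thus shows that the differences were equal in the 2 years. In 558 probes the high cultivars lay beyond all low cultivars on the same side in both years, 311 higher and 247 lower. These 558 are 6.76% of the shared probes, and the 14 other splits gave between 44 and 578, with a median of 143.5. Of the 255 among the 558 that differed by at least 1 log2 unit, 100 were higher and 155 lower. Chance gives 13.3% for a single year, where 18.6% (1537 probes) was seen in 2009 and 17.6% (1453) in 2010. Other splits of the cultivars gave up to 2816 probes in 2009 and 1610 in 2010, so this excess is not particular to high against low.

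**Figure D2:**
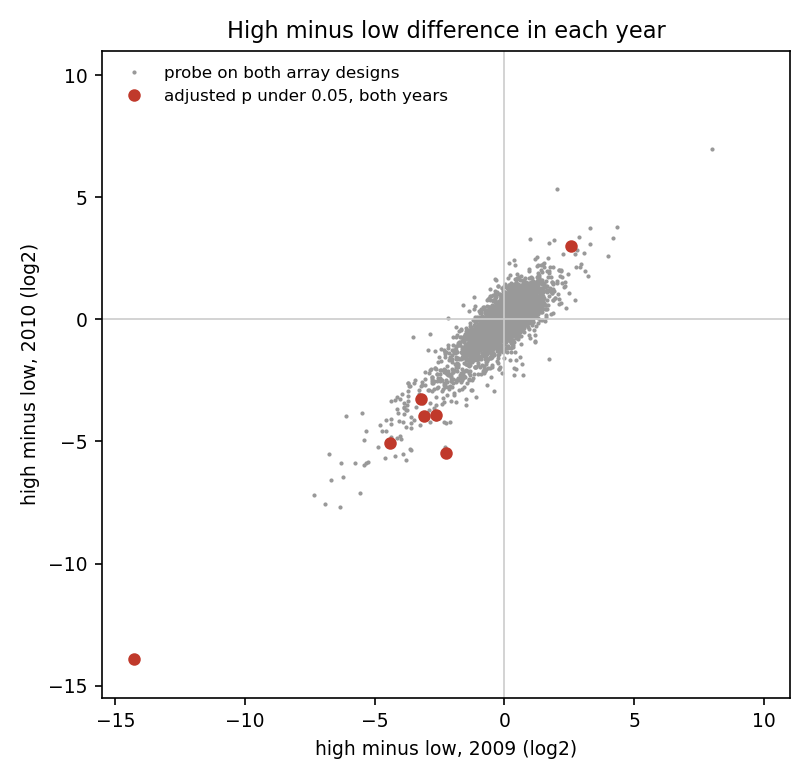
High minus low difference (log2) of each of 8257 shared probes in 2009 (x axis) and 2010 (y axis); each point is 1 probe, and red points are the 7 probes called over both years. The differences correlate at r = 0.84, and the red point at the lower left is NFR2_08_57mR, which was not well above background in the high cultivars and was at least 10606-fold lower in 2009 and at least 7250-fold lower in 2010.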

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

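None of 30 sets of low-group values held a cultivar apart from the others by Dixon's ratio, where chance gives about 1.5. The sets were those of the named probes and of array quality in each year. The named probes were picked by small p and lack of overlap, which favours low cultivars that agree. The absence of flags among them therefore shows little. No probe was called for a change between years. Of the tests below, those on detection floors and on the other probe of a clone were set before their results were seen. Those on the 6 identifier-named probes, batch, parentage and other splits were chosen afterwards. The fits with the parentage covariate, and with the slide as a term in 2009, were planned, but their use to weigh these causes was not.

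Probes dark in both high cultivars and detected in all 4 low cultivars numbered 112 in 2009, 22 in 2010 and 3 in both years. Those detected in the high cultivars alone numbered 8 in 2009 and 73 in 2010. Other pairs of cultivars gave up to 68 dark probes in 2009 and 560 in 2010. Up to 65 in 2009 and 76 in 2010 were detected in another pair alone. The counts of 2010 are thus not particular to the high cultivars. For the 3 of both years, among them NFR2_08_57mR, the median difference was -4.60 log2 units with every array at its detection floor. This argues against dim arrays for these 3. A base difference under the probe could not be tested for them, since 0 of their clones had another 2009 probe detected in all 4 low cultivars. The same tests with the same bounds were then extended to the 112 of 2009, whose median at the detection floor was -0.99, just short of the bound of -1, and La France had the dimmest array of that year, so dim arrays may account for many of them. At the detection floor, 56 of the 112 (50%) still lay below -1. The other probe of the clone, usable for 60, had a median difference of -0.042, as a base difference under a single probe or a dim array would each give. For 12 of the 60 the other probe lay below -1, so the median does not speak for every clone. A base difference, a dim array and a difference in expression remain open, as does RNA of another organism, which was not tested.

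The 6 identifier-named probes were bright in La France and Taiheiyou, its offspring per the label, and dark in the 4 low cultivars, including the La France × Housui hybrid. La France's array detected 85.1% of probes and the best low array 84.7%, too close to decide anything. The smallest of the 6 bounds was 53.9-fold at the low arrays' detection floors, which argues against dim arrays. The La France minus Taiheiyou difference spanned 1.65 log2 units over the 6 probes, but with 1 array per cultivar this decides nothing on a single transcript binding all 6, which remains open. Alleles or transcripts passed from La France to Taiheiyou and not to the La France × Housui hybrid remain a hypothesis, as does a tie to parthenocarpy, and neither was tested.

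The calls of 2010 were weighed against batch and parentage. Within the scan day that holds both groups, the difference of the 33 called probes was a median 0.99 of that over 6 arrays, between 0.91 and 1.09. High and low arrays of the same scan day thus differed by about as much, so scan day alone does not give the difference of these probes. With European parentage as a covariate the difference was a median 0.98 of that without, between 0.77 and 1.11. A linear effect of the assumed share of parentage thus does not alone give the difference of these probes either. A call needs the 4 low cultivars to agree, so ratios near 1 follow largely from the choice of these probes. The ratios say nothing of other probes, and other differences between the cultivars remain open. The fits called 18 probes (10 among the 33) and 11, with fewer arrays or an added term.

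The 6 cultivars allow 15 splits into 2 and 4, too few for a share under 0.05. As many calls came from 3 splits in 2009, 2 in 2010 and 3 over both years, the real split included. The real split gave 5, 33 and 7 calls and the highest other, La France and LeConte, 26, 48 and 28. The split that follows the batch gave 6 calls in 2009, 11 in 2010 and 2 over both years, with r = 0.64 between the years and 578 probes without overlap in both years, against 558 for the real split. With the slide as a term 4 probes were called between high and low in 2009, 2 of them among the 5.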

How the results depend on the processing

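The alternatives with batch as a term in 2010 and over both years, the batch of 4 cultivars alone and the detection floor were chosen after seeing the data. The count stayed within 1.5 times in 9 of 18 settings for 2009, 9 of 18 for 2010 and 12 of 20 for both years. Among these settings, the minimum difference and the deposited value tables could hardly change the count. Every call exceeded that minimum, and those tables hold nearly the same values, centred for each probe. The probes called could also differ, as with detection on all 6 arrays in 2009 (7 called, 1 of them among the 5). The calls of 2009 (5) became 13 with normexp (1 higher, 12 lower), 12 with trend and robust and 2 with the parentage covariate. Those of 2010 (33) became 5 with detection on all 6 arrays, 11 with the covariate, 16 with scan day as a term (9 higher, 7 lower) and 18 in the batch of 4 cultivars (8 higher, 10 lower). Those of both years (7) became 1 with the covariate, 2 with batch as a term (1 higher, 1 lower), 37 with 12 arrays and the cultivar as a random block and 37 in the 3 hybrids, where arrays of a cultivar count as replicates. The covariate and batch terms leave fewer degrees of freedom, and the other causes were not tested. Leaving out each cultivar gave between 2 and 65 calls in 2009, 13 and 220 in 2010 and 2 and 88 over both years. The highest count came without Taiheiyou each time, where La France is assumed to vary like the low cultivars. The change between years stayed at 0 calls by limma under every alternative run and without each cultivar, and cultivar identity kept a mean r of 0.65 with quantile scaling and 0.53 with detection on all 12 arrays. The 11 probes of the naming rule kept their direction in all 215 values, with 38 losing and 2 gaining the threshold. No paired analysis was possible because no cultivar is in both groups and the labels give no replicate numbers. The slide could not be a term in 2010, and the gene list tests were not run, since no probe has a gene name. Signal near background limits the dark probes to bounds.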

Other observations

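All tests in this part were chosen after the values were seen. The median position of the hybrids lay between their parents over probes that part the parents. Probes were chosen where La France and the other parent differed by at least 2 log2 units in a year and by at least 1 the same way in the other, where the hybrid was read on the linear scale, with 0 at the Japanese parent and 1 at La France. Taiheiyou had a median position of 0.51 over 615 probes chosen in 2009 and 0.45 over 553 chosen in 2010. The La France × Housui hybrid had 0.42 over 647 probes and 0.53 over 619. The probes were picked for parents far apart, and no cultivar of other parentage was read this way. These medians therefore do not show inheritance from the parents. The probes spread widely, and only 43.9% to 51.4% of them had a position between 0.25 and 0.75. The position differed by direction. Where La France was higher, the medians were 0.33 and 0.31 for Taiheiyou and 0.25 and 0.31 for the La France × Housui hybrid, nearer to the Japanese parent. Where La France was lower, they were 0.56 and 0.55 for Taiheiyou and 0.45 and 0.58 for the La France × Housui hybrid. La France was higher at 187 of the 615 probes. The cause was not tested.

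Probes of 2010 named by public sequence identifiers differed between cultivars more often than clone-named probes. Of 555 such probes tested, 104 (18.7%) spanned over 5 log2 units between the lowest and the highest cultivar, against 583 of 18089 clone-named probes (3.22%). The odds ratio was 6.92 (Fisher's exact test, two-sided, p = 1.3e-44, with probes as units, which are not independent). Many of these spans reach into signal below background. With every value raised to the highest detection floor of the year, 90 (16.2%) and 395 (2.18%) still spanned over 5. Of the 104 probes, leaving out repeat copies, 31 were well above background in all 6 cultivars and 16 in all but Housui. Another 12 were so in La France, LeConte and Taiheiyou alone, 6 in La France and Taiheiyou alone and 5 in La France and LeConte alone. A further 5 were so in the La France × Housui hybrid, Housui and Okusankichi alone.

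In 2010, 560 probes were dark in Housui and Okusankichi alone, which were scanned on the second day, and 55 in 2009. The lowest signals of these 2 arrays in 2010 were 7.73 and 5.09, against 1.38 to 1.79 on the others. In 201 of the 560 the other 4 arrays lay above the highest detection floor of the year.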
